A study of Homo sapiens with 8 samples.

How the data were processed

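RNA was profiled by sequencing in 8 libraries that the labels assign to HuLEC-5A, an immortalised line of human lung microvascular endothelial cells. The labels put the libraries in 2 groups, cells given a control guide (sgControl) and cells given a guide against MFSD7C (sgMFSD7C), with replicates numbered from 1 to 4 in each. MFSD7C is an older name of FLVCR2. The labels do not say whether the replicates are separate cultures, nor give the guide sequence, so p-values here measure the spread between these libraries, which may be technical.

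The authors deposited FPKM values (fragment counts scaled by gene length and by the reads of the library) in 2 tables, and the gene length column in each gives the length used. One table holds sgControl 1 and sgMFSD7C 1 and is called the single pair. Its knockout column was matched to sgMFSD7C 1 by a close but not identical name in the labels, the only one of its kind, so this match is an inference. The other holds replicates 2 to 4 of both groups and is called the replicated table. It also holds 3 columns that match no sample in the labels, which enter no result. A correlation that included them was computed when the tables were opened and is not reported here. A wrong label of sgControl 4 cannot be ruled out. The aligner and counter are not given in the sources used here. The submitters' processing notes name the builds hg38 and GRCm38. All 54532 gene identifiers in each table are mouse Ensembl identifiers with mouse symbols. The largest gene end on chromosome 1, 195323493, lies past the end of chromosome 1 in the later mouse build, and coordinates are given as the files give them, on GRCm38. No mouse genome was used here, so the species of the RNA was not tested by alignment. For the replicated libraries the levels given below argue against RNA of the labelled human line. For the single pair the question could not be settled.

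In the column of each of the 8 libraries the FPKM value times gene length was a whole multiple of 1 step, to within 0.01 of a whole number, for 100% of the values above 0, so whole reads per gene could be recovered. The effective library size behind the values was between 0.977 and 1.04 times the recovered reads. Recovered reads gave the depth, the exact 95% Poisson and binomial intervals and 1 alternative fit. These intervals cover counting error only.

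The 2 tables were normalized separately, so tests were made within the replicated table. Genes with FPKM of at least 1 in at least 3 libraries were kept, and log2(FPKM + 1) was compared between groups with limma 3.58.1 in R 4.3.3, with an intensity trend, moderated two-sided tests and Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. The design also named a count test, to be used only if the tables held counts, and it was not needed.

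A set of 38 gene lists, the tests and most alternatives were fixed before the data were examined. The list symbols are human. Of 950 distinct symbols, 901 were matched to a mouse gene after the tables were seen, 49 of these through an older symbol, 5 through a mouse name chosen by hand and the rest by the same letters. The other 49 were not matched. A shared symbol does not make the genes equivalent in both species. Lists with at least 5 measured members were tested with camera from limma, with a preset correlation of 0.01 between genes, and adjusted over the lists. Camera with an estimated correlation and fry, which asks whether the members of a list move on balance 1 way without comparing them with other genes, were alternatives. Beside each list test stands the number of members called over all genes tested, and for the main lists the number called when adjusted over the list alone.

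Named genes followed a rule fixed in advance: Flvcr2 and Flvcr1; the 12 largest rises and 12 largest falls among called protein-coding genes with a mean of at least 5 FPKM in 1 group and no overlap between groups; in each list described, up to 4 called members with the largest change or, if none was called, the 2 with the smallest p; and Gpx4, Slc7a11, Acsl4, Tfrc, Fth1, Hmox1, Aifm2 and Ptgs2. In the single pair it added the 6 highest and 6 lowest ratios among protein-coding genes with FPKM of at least 10. With 1 library per group, the single pair was described without a test, and a list there was placed among 10000 random lists of the same size matched on mean expression.

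The fit was tested on simulated reads for the replicated comparison, with 12654 genes, the real means and depths and a dispersion of 0.02. It called in the right direction 15.6% of 64 genes changed 1.5-fold, 75% of 64 genes changed 2-fold and 98.5% of 66 genes changed 4-fold, and it called 19 of 12460 unchanged genes. The list test called 5 of 5 raised lists and 1 of 20 unchanged lists. The simulated genes were drawn independently at a single dispersion, with no library set apart. The data differ in this, so these rates need not hold for them.

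Alternatives were other pseudocounts, filters, scalings and variance settings, protein-coding genes alone, the replicate number as a block, all 8 libraries with the table as a term, each library left out in turn, and the 2 other list tests. A limma-voom fit to the recovered reads was added after the data were seen. Reads of genes with processed pseudogenes or near-identical paralogs can be lost or split in counting. Gapdh, with many such copies, stood at 2.77 ± 1.19 FPKM (SD, n = 3) in the sgControl group, so levels of Fth1, the ribosomal protein genes and pairs such as Ifit3 and Ifit3b are uncertain. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.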

Results

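Gene expression was measured in 8 RNA-sequencing libraries, 4 labelled as control-guide cells (sgControl) and 4 as cells with a guide against MFSD7C (sgMFSD7C), the gene now called FLVCR2. The study's title asks whether MFSD7C protects the lung from hemolysis by limiting ferroptosis, an iron-dependent cell death driven by lipid peroxidation. The replicated table holds 3 libraries per group, with 13467469 to 17001918 recovered reads each and 21436 to 22820 genes above 0. The single pair holds 1 library per group, with 52377 reads on 1426 genes for sgControl 1 and 49972 reads on 1380 genes for sgMFSD7C 1.

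The targeted gene, Flvcr2 (ENSMUSG00000034258, chromosome 12, 85746539 to 85813585), was under 1 FPKM in the 6 libraries of the replicated table. Its level was 0.206, 0.0188 and 0.0961 FPKM in sgControl 2, 3 and 4, from 10, 1 and 5 reads. In sgMFSD7C 2, 3 and 4 it was 0.308, 0.0363 and 0.0576 FPKM, from 19, 2 and 3 reads. The levels of the groups overlapped. The exact 95% Poisson intervals ran from 0.0253 to 5.57 reads in sgControl 3 and from 4.80 to 18.4 in sgControl 2, and from 0.242 to 7.22 reads in sgMFSD7C 3 and from 11.4 to 29.7 in sgMFSD7C 2. It did not reach 1 FPKM and was not tested. It was listed at 0 in both libraries of the single pair, where 0 reads allow up to 3.69 reads at the upper 95% limit, or 20.6 FPKM in either library, so a level like that of Flvcr1 was not detectable there. At these counts the transcript does not check the labels, and a guide need not lower the transcript it cuts. In the replicated table Flvcr2 was near 0 already in the controls, with upper 95% limits of 0.379, 0.105 and 0.224 FPKM in sgControl 2, 3 and 4. Whether differences between the groups follow from loss of MFSD7C therefore cannot be told. The related heme exporter Flvcr1 (ENSMUSG00000066595, chromosome 1, 191005847 to 191026158) rose from 5.83 ± 0.386 to 8.87 ± 0.333 FPKM (SD, n = 3 each; limma log2 fold change 0.53, SE 0.0827, adjusted p = 0.017). Its adjusted p reached 0.102 when 1 library was left out and the call was lost without sgControl 2, sgMFSD7C 2, sgMFSD7C 3 or sgMFSD7C 4.

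The labels name a human endothelial line, and both tables count mouse genes. For the replicated libraries, on which every test rests, the endothelial and mitochondrial values below argue against RNA of that line. Which cells these libraries hold was not tested. In the replicated table, 5 of 31 endothelial identity genes reached 1 FPKM in every library. Pecam1, an endothelial adhesion molecule, averaged 0.106 ± 0.0131 FPKM in sgControl and 0.0839 ± 0.0512 FPKM in sgMFSD7C (SD, n = 3), and Cdh5, the endothelial cadherin, 0.0271 ± 0.0332 and 0.0972 ± 0.0601 FPKM. The collagen gene Col1a1 averaged 163 ± 45.5 and 97.8 ± 3.52 FPKM, and the intermediate filament gene Vim 440 ± 55.2 and 475 ± 8.38 FPKM. The epithelial marker Epcam was listed at 0 in all 6 libraries and the leukocyte marker Ptprc was at 0.0134 ± 0.0169 and 0.0069 ± 0.00382 FPKM. Other members of these marker lists were higher. Eng had the highest mean of the endothelial identity genes, 69.9 FPKM in sgControl and 59.3 in sgMFSD7C. Of 18 leukocyte markers, 4 reached 1 FPKM in every sgControl library and 3 in every sgMFSD7C library. The highest was Cd74, with means of 151 and 104 FPKM. Mouse mitochondrial transcripts took 1.01% to 1.63% of the reads of each library, with 58770 to 107062 reads on mt-Co1.

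Among the 6 libraries of the replicated table, the sgMFSD7C libraries lay close together and sgControl 4 lay apart from the other controls. Across genes, Pearson's r of log2(FPKM + 1) was 0.983 to 0.986 between sgMFSD7C libraries and 0.983 between sgControl 2 and 3. It was 0.960 and 0.957 between sgControl 4 and those 2 controls, about the level between groups, 0.956 to 0.963. Read counts of the closest libraries differed beyond counting noise, with chi-square over degrees of freedom of at least 2.74, so no library was a copy of another. Genes are not independent replicates, and these correlations only describe the libraries.

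**Figure D1:**
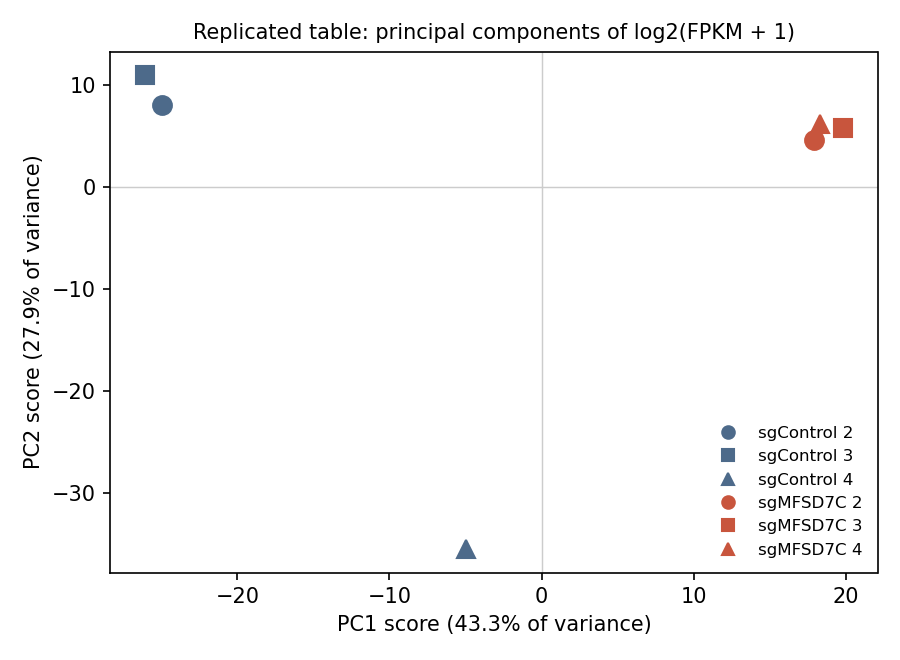
Principal component scores of the 6 libraries of the replicated table on log2(FPKM + 1) of the genes tested; each point is a library, colour gives the group and marker shape the replicate number. PC1 (43.3% of the variance) places the sgControl libraries between -26.1 and -4.99 and the sgMFSD7C libraries between 17.9 and 19.8, and PC2 (27.9%) places sgControl 4 at -35.4 while the other 5 libraries lie between 4.59 and 10.9.

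Between sgMFSD7C and sgControl cells, 25 of 30 measured interferon response genes fell, and 8 of 24 measured NRF2 targets rose (14 without sgControl 4, 4 without sgControl 2, sgControl 3 or sgMFSD7C 3, and 3 without sgMFSD7C 2 or 4). Hmox1, which encodes the heme-degrading enzyme heme oxygenase 1, rose from 33.4 ± 13.2 to 173 ± 2.38 FPKM (SD, n = 3 each), 5.38-fold. Ifit3, an interferon-induced antiviral gene, fell from 141 ± 45.7 to 13.6 ± 1.15 FPKM, and Isg15, an interferon-induced ubiquitin-like protein, fell from 228 ± 18.8 to 35.6 ± 5.3 FPKM. Id2 and Id3, transcriptional regulators induced by BMP signalling, fell from 17.8 ± 5.94 to 2.42 ± 0.357 FPKM and from 36 ± 14.8 to 4.49 ± 0.706 FPKM.

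Of 12581 genes tested with limma, 862 (6.85%) were called, 355 higher and 507 lower in sgMFSD7C. Of these, 172 changed by at least 1 on the log2 scale, 21 up and 151 down. None of the 862 showed overlapping groups, and 32.4% of all genes tested did not overlap, against 10% expected by chance for 3 libraries against 3. The count changed with each library left out. It was 3332 without sgControl 4, 218 without sgControl 2, 265 without sgControl 3, 150 without sgMFSD7C 2, 201 without sgMFSD7C 3 and 152 without sgMFSD7C 4. A fit without 1 library has less power, so a lost call need not mean that a gene rests on that library. A set of 137 genes, 18 higher and 119 lower, was called with all 6 libraries and in each of these 6 smaller fits. A limma-voom fit to the recovered reads, chosen after seeing the data, called 1254 genes, 53% of them higher against 41.2% in the limma fit to FPKM.

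**Figure D2:**
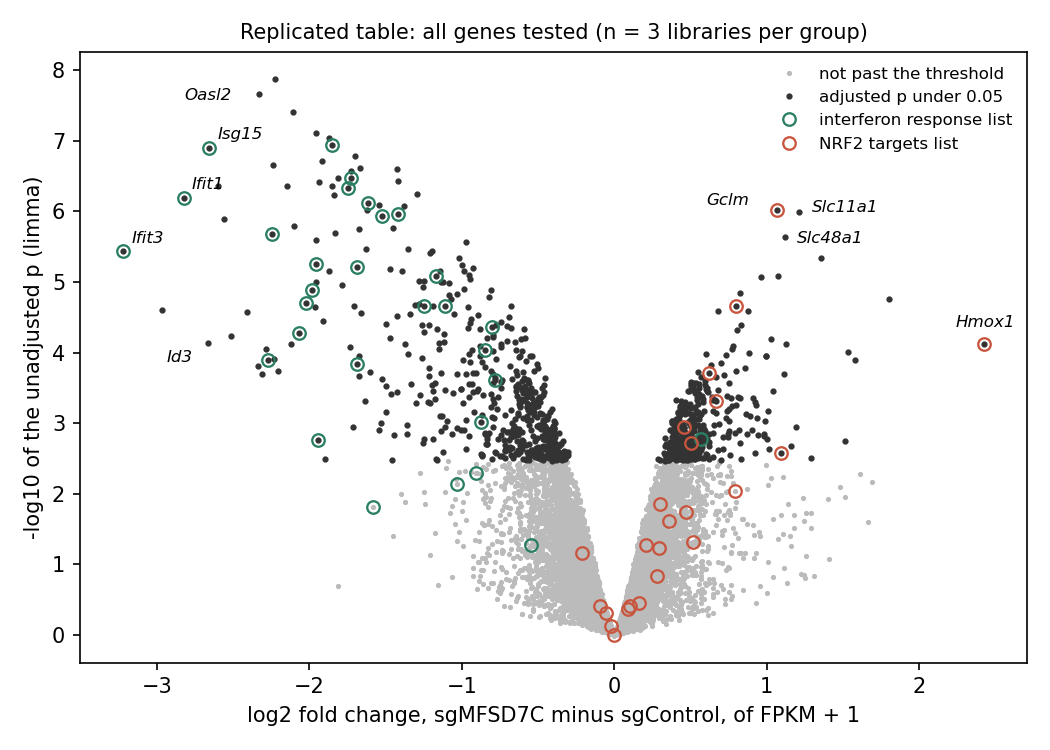
Log2 fold change of FPKM + 1 (sgMFSD7C minus sgControl, n = 3 libraries per group) against -log10 of the unadjusted limma p for the 12581 genes tested; black points are the 862 called genes, and rings mark members of the interferon response and NRF2 target lists. The called interferon members lie to the left, down to -3.22 for Ifit3, except Ifi27 at 0.57, and Hmox1 lies furthest right of the NRF2 members at 2.43.

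Among the 12 largest rises, Slc48a1, which moves heme out of the lysosome, rose 2.17-fold from 74.5 ± 5.3 to 163 ± 0.187 FPKM (log2 fold change 1.12, SE 0.0791, adjusted p = 0.000748). Slc11a1, a phagosomal exporter of iron and manganese, rose 2.32-fold to 52.6 ± 3.35 FPKM (adjusted p = 0.000423), and the zinc importer Slc39a10 2.16-fold to 9.94 ± 0.384 FPKM (adjusted p = 0.0128). Gclm, a subunit of the enzyme that starts glutathione synthesis, rose 2.1-fold (adjusted p = 0.000418), and Pgd, of the pentose phosphate pathway, 2.13-fold (adjusted p = 0.045). The others were Hmox1, the membrane protein gene Tm4sf19 (2.56-fold), the esterase gene Esd (2.18-fold), the integrin gene Itgb7 (2.1-fold), the lipid carrier Apoe (2.04-fold), the arsenite-induced Zfand2a (2.02-fold) and the immune receptor Havcr2 (2.01-fold), with adjusted p from 0.00121 to 0.0365. When 1 library was left out, Slc39a10, Pgd, Zfand2a and Havcr2 lost their calls, each without sgControl 2 or any 1 of the 3 sgMFSD7C libraries, and Pgd also without sgControl 3, with adjusted p of up to 0.072, 0.155, 0.105 and 0.141. The other 8 stayed called in every such fit.

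Among the 12 largest falls, 10 were genes known to be induced by interferon or belonging to such families. Besides Ifit3 and Isg15 they were Ifit3b, Ifit1, Usp18, Ifi44 and Oasl2, the immunity-related GTPase genes Iigp1 and Irgm2, and Slfn2. Their log2 fold changes ran from -3.22 for Ifit3 to -2.25 for Ifi44, with adjusted p from 0.000135 for Oasl2 to 0.00943 for Usp18. The other 2 were Id3 (-2.66, adjusted p = 0.00693) and Id2 (-2.41, adjusted p = 0.00354). Usp18 lost its call without sgMFSD7C 2, 3 or 4, with an adjusted p of up to 0.0564, and the other 11 kept theirs in each fit that left 1 library out. Ifit3 and Ifit3b are near-identical, so the split of reads between them is uncertain.

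Camera at the preset correlation called 15 of 31 lists, and fry called 5. In a check made after the results were seen, other splits of the 6 libraries into 3 and 3 called 11 to 17 by camera. A list call by camera, here and below, therefore does not by itself tell the real grouping from others. The interferon response list was called lower. Of its 30 measured members, 25 fell, 1 rose (Ifi27, 0.57, chosen after its value was seen and called in the fits without 1 library only without sgControl 4) and 4 did not pass the test, and adjusted over the list alone 28 fell and 1 rose. The mean log2 fold change was -1.56 and the median -1.65 (camera adjusted p = 1.36e-28; adjusted p = 0.247 with an estimated correlation; fry adjusted p = 0.00204). Each sgMFSD7C library lay 1.5 to 1.63 below the mean of the controls over the members, while sgControl 4 lay 0.30 below it. A group of 19 members was called in every fit that left 1 library out. The list of class I antigen presentation, which interferon also induces, fell with 4 of 9 members, the peptide transporter genes Tap1 (-0.99) and Tap2 (-0.42) and the immunoproteasome genes Psmb9 (-0.87) and Psmb8 (-0.71) (camera adjusted p = 0.00225; adjusted p = 0.34 with an estimated correlation; fry adjusted p = 0.0277). Adjusted over the list alone 6 fell. The count of 4 was 1 without sgControl 2 or any 1 sgMFSD7C library. Tap1 kept its call in every fit without 1 library. Tap2, Psmb9 and Psmb8 lost theirs without sgControl 2 or any 1 sgMFSD7C library, and Tap2 also without sgControl 3, with adjusted p of up to 0.174, 0.109 and 0.122.

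Of the ferroptosis genes named in advance, Hmox1 was called and 7 were not. Gpx4, the enzyme that reduces lipid peroxides, was at 182 ± 6.6 FPKM in sgControl and 170 ± 13.2 FPKM in sgMFSD7C (SD, n = 3; limma adjusted p = 0.525). Slc7a11, the cystine importer, averaged 5.99 ± 2.08 and 10.7 ± 0.132 FPKM (log2 fold change 0.79, adjusted p = 0.08), with 3.63 FPKM in sgControl 4 as the lowest value. Acsl4, which makes phospholipids prone to peroxidation, averaged 11 ± 4.16 and 7.28 ± 0.402 FPKM (adjusted p = 0.231), with 15.8 FPKM in sgControl 4 as the highest value, and its log2 fold change of -0.48 was -0.21 without that library. The transferrin receptor Tfrc averaged 55.7 ± 7.22 and 42.6 ± 3.56 FPKM (adjusted p = 0.103), and the ferritin heavy chain Fth1 3040 ± 96.9 and 3750 ± 41.7 FPKM (adjusted p = 0.1). Aifm2, a ubiquinone reductase also called FSP1, was at 6.31 ± 0.327 and 6.51 ± 0.496 FPKM (adjusted p = 0.826), and Ptgs2, a prostaglandin synthase, at 4.52 ± 3.06 and 3.07 ± 0.433 FPKM (adjusted p = 0.811). Without sgControl 4, 4 of these passed: Slc7a11 was higher (0.52, adjusted p = 0.00462), Fth1 higher (0.33, adjusted p = 0.0426), Tfrc lower (-0.47, adjusted p = 0.0131) and Ptgs2 lower (-0.84, adjusted p = 0.00469). The log2 fold change of Ptgs2 was -0.22 with all 6 libraries and above 0 without sgControl 2 (0.05) or sgControl 3 (0.12), and that of Aifm2, 0.04, was below 0 without sgMFSD7C 4 (-0.01).

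The list of ferroptosis suppressors was called higher, with 3 of 20 measured members called up and none down, and adjusted over the list alone 8 up and 1 down. The called members were Gclm, Gclc, the catalytic partner of Gclm (0.67, adjusted p = 0.0197), and the ferritin light chain Ftl1, from 488 ± 26 to 751 ± 38 FPKM (0.62, adjusted p = 0.0125). The list call (camera adjusted p = 0.0202) was not made with an estimated correlation (camera adjusted p = 0.266) or by fry (adjusted p = 0.0675). It was lost without sgControl 4, at a camera adjusted p of 0.0951, where 8 members were called up and 3 down. Without sgMFSD7C 2 or 4, 1 was called up. Gclc lost its call without sgControl 2 or any 1 sgMFSD7C library and Ftl1 without sgControl 3, sgMFSD7C 2 or sgMFSD7C 4, with adjusted p of up to 0.10 and 0.0868. The list of ferroptosis drivers had 1 member called up, Hmox1, and 2 called down, the ether lipid enzyme Far1 (-0.64) and the acyl-CoA synthetase Acsf2 (-0.43), of 25 measured (camera adjusted p = 0.451). Far1 lost its call without any 1 sgMFSD7C library and Acsf2 without any library but sgControl 4, with adjusted p of up to 0.0762 and 0.174. Without sgControl 4 the counts were 6 up and 5 down. Adjusted over the list alone the counts were also 1 and 2. The median of that list was -0.13 and its mean 0.00026. Of 10 measured ferroptosis-associated transcripts, 1, Hmox1, rose over all genes tested, and adjusted over the list alone 2 rose and 1 fell (camera adjusted p = 0.981, direction down, median -0.24, mean 0.08). Without sgControl 4, 2 were called up and 5 down, and the mean was -0.21 (adjusted p = 0.0925).

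The list of NRF2 targets, genes of the antioxidant response, was called higher. Of 24 measured members, 8 rose and none fell, and adjusted over the list alone 12 rose and none fell. The mean log2 fold change was 0.45 (camera adjusted p = 5.15e-06; adjusted p = 0.149 with an estimated correlation; fry adjusted p = 0.000107). The 4 largest changes among the called members were Hmox1, Pgd, Gclm and the sulfiredoxin gene Srxn1, which rose 1.74-fold from 58.1 ± 4.34 to 102 ± 2.03 FPKM (adjusted p = 0.00316). All 3 sgMFSD7C libraries lay 0.44 to 0.46 above the control mean over the members and the 3 controls between -0.04 and 0.03. Single members of sgControl 4 differed from the other controls in both directions, with Hmox1 at 18.3 FPKM against 38.9 and 42.9 FPKM and Pgd at 31.6 FPKM against 18.2 and 15.2 FPKM in sgControl 2 and 3. Hmox1, Gclm and Srxn1 were called in each fit that left 1 library out, and Pgd was called only without sgControl 4 (adjusted p of up to 0.155). The number of members called was 14 without sgControl 4, 4 without sgControl 2, sgControl 3 or sgMFSD7C 3, and 3 without sgMFSD7C 2 or 4, all higher.

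Heme and iron lists had members called in both directions and were not called as lists. In the list of heme synthesis, breakdown and transport, 3 of 24 measured members rose (Hmox1, Slc48a1 and Flvcr1) and 1 fell, the scavenger receptor gene Lrp1 (-0.40, adjusted p = 0.0313, and up to 0.151 in the fits without 1 library, of which only that without sgControl 4 called it). Adjusted over the list alone, 5 rose and 3 fell (camera adjusted p = 0.981, direction up, mean 0.10, median -0.07). Without sgControl 4, 7 heme genes were called up and 5 down. Flvcr1 lost its call without sgControl 2 or any 1 sgMFSD7C library (adjusted p of up to 0.102). Of 22 iron genes, Ftl1 rose and the BMP target Id1 fell (-1.67, adjusted p = 0.0131, and up to 0.066 in the fits without sgControl 3 or any 1 sgMFSD7C library, where it lost its call), with the same counts adjusted over the list alone. Without sgControl 4, 3 iron genes were called up and 5 down, and none was called without sgControl 3, sgMFSD7C 2 or sgMFSD7C 4. The camera direction of this list was down (mean -0.09, adjusted p = 0.981), its median was 0.02 and fry's direction was up.

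**Figure D3:**
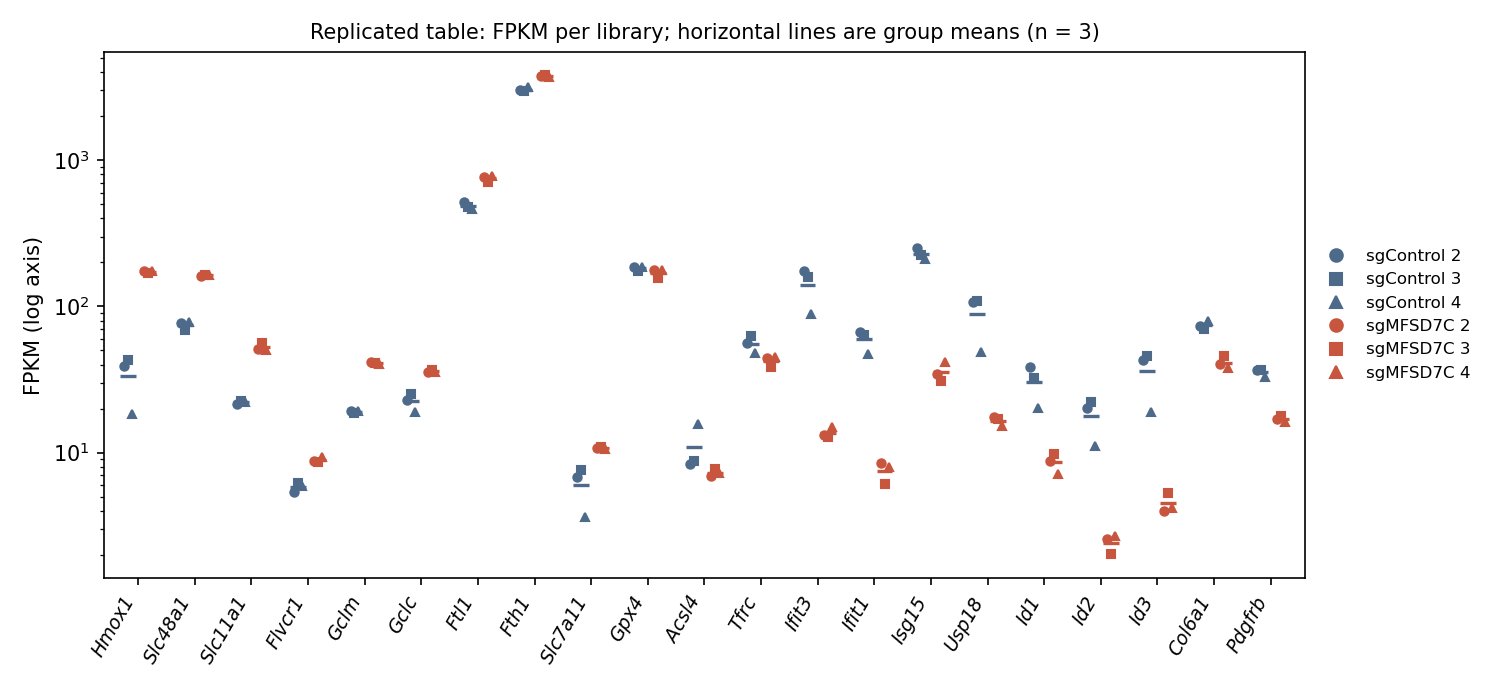
FPKM per library (log axis) of genes named in the text, in the 3 sgControl and 3 sgMFSD7C libraries of the replicated table; points are libraries and horizontal lines group means. Hmox1 lies at 173 FPKM on average in sgMFSD7C against 33.4 in sgControl, while Gpx4 lies at 170 against 182.

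Few genes of the other stress lists were called, and sgControl 4 stood apart from the other controls in each of these lists. The heat shock list was called higher, with Hsph1 (0.77) and Hspb8 (0.54) called of 14 and 4 up adjusted over the list alone (camera adjusted p = 0.00311; adjusted p = 0.759 with an estimated correlation), and sgControl 4 lay 0.34 above the control mean over the members, level with the sgMFSD7C libraries. p53 targets were called higher, with Phlda3, a repressor of AKT, (0.60) and the cyclin G1 gene Ccng1 (0.57) called of 22 and 7 up adjusted over the list alone (adjusted p = 0.0202; adjusted p = 0.759 with an estimated correlation; 0.463 without sgControl 4). Over its members sgControl 2 and 3 lay 0.19 and 0.16 above the control mean, level with sgMFSD7C, and sgControl 4 lay 0.35 below. The integrated stress response list of ATF4 was called lower, with 1 of 32 called, the mitochondrial enzyme gene Pck2 (-0.50; list adjusted p = 0.0447; adjusted p = 0.989 with an estimated correlation). Its call was lost without sgControl 2, sgControl 3, sgMFSD7C 2 or sgMFSD7C 4, with an adjusted p of up to 0.485, and sgControl 4 lay 0.54 below the control mean over the members. The unfolded protein response list was not called (adjusted p = 0.981), with the chaperone gene Dnajb9 up (0.76). Without sgControl 4 that list was higher in sgMFSD7C (mean 0.22, adjusted p = 0.00128). Of the fits without 1 library, Hsph1, Hspb8, Ccng1 and Pck2 were called only without sgControl 4, Phlda3 only without sgControl 2 or 4, and Dnajb9 only without sgControl 4 or sgMFSD7C 3, with adjusted p of up to 0.157. Without sgControl 4, 8 heat shock genes were called up, 6 p53 targets up and 5 down, 1 gene of the ATF4 list up and 22 down, and 9 of the unfolded protein response up.

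The lists of TGF-beta targets and of matrix genes were called lower, with a minority of members called. The TGF-beta and mesenchymal list had 5 of 19 members down and none up (mean -0.71; camera adjusted p = 1.69e-05; adjusted p = 0.247 with an estimated correlation; fry adjusted p = 0.0319; 8 down adjusted over the list alone), led by Id3, Id2, Id1 and the matrix protein gene Tgfbi (-1.01, from 58.9 ± 13.3 to 28.4 ± 1.77 FPKM). The Id genes are better known as targets of BMP signalling, and Id2 and Id3 kept their calls without each library in turn. In the extracellular matrix list 8 of 27 fell and none rose (mean -0.34; adjusted p = 7.28e-06; adjusted p = 0.402 with an estimated correlation; 1 up and 16 down adjusted over the list alone), including Sparcl1 (-1.10), the collagen VI genes Col6a1 (-0.84) and Col6a2 (-0.74) and the protease inhibitor Timp2 (-0.60). Of 9 fibroblast markers 1 fell, the growth factor receptor Pdgfrb, from 35.5 ± 2.07 to 17 ± 0.838 FPKM (list adjusted p = 0.0213; adjusted p = 0.266 with an estimated correlation; 0.0951 without sgControl 4). Col6a1 and Pdgfrb were called in each fit that left 1 library out. Id1, Tgfbi, Sparcl1, Col6a2 and Timp2 were not, with adjusted p of up to 0.066, 0.0892, 0.112, 0.0799 and 0.173, in turn. Id1 lost its call without sgControl 3 or any 1 sgMFSD7C library, Tgfbi without any 1 sgMFSD7C library, Col6a2 without sgControl 2, sgMFSD7C 2 or sgMFSD7C 4, and Sparcl1 and Timp2 without any library but sgControl 4. Without sgControl 4, 1 TGF-beta list gene was called up and 12 down, 2 matrix genes up and 14 down, and 2 fibroblast markers up and 6 down. Without sgMFSD7C 2, 3 or 4 the TGF-beta list had 3, 3 and 3 called down and the matrix list 1, 3 and 1, and without sgControl 2 or 3 the matrix list had 1 and 2, with none called up in these fits.

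Of 31 endothelial identity genes 5 were measured, and Pecam1 and Cdh5 were near 0, so that list says little about endothelial identity. The endothelial identity list, with 5 measured members, was called lower (mean -0.53; camera adjusted p = 0.0202; adjusted p = 0.266 with an estimated correlation; fry adjusted p = 0.0395), and 1 member was called, the adhesion molecule gene Mcam, from 12 ± 0.561 to 5.74 ± 0.802 FPKM. Of 12 angiogenesis genes 3 fell, Vegfa (-0.63), Efnb2 (-0.59) and Pgf (-0.58) (list adjusted p = 0.0104; adjusted p = 0.368 with an estimated correlation). The junction list was not called (adjusted p = 0.981; mean -0.05, median 0.005), with the plakoglobin gene Jup down (-0.78), nor was the adhesion and inflammation list (adjusted p = 0.981; 0.0385 and lower in sgMFSD7C without sgControl 4), with the chemokine gene Cx3cl1 down (-0.56) and Nfkb2 up (0.53). Mcam and Jup were called in each fit that left 1 library out, and Vegfa, Efnb2, Pgf, Cx3cl1 and Nfkb2 only in the fit without sgControl 4, with adjusted p of up to 0.165. Without sgControl 4, 3 endothelial identity genes were called down, 1 angiogenesis gene up and 7 down, 3 junction genes up and 2 down, 2 adhesion genes up and 8 down, and 4 coagulation genes down. No member of the coagulation list was called with all 6 libraries (list adjusted p = 0.758; 0.0312 and lower without sgControl 4), the smallest p being those of Anxa2 (-0.24) and Procr (0.32, and 0.18 without sgControl 4).

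Few genes of the metabolic lists were called. No glycolysis gene passed over all genes tested, Eno2 (-0.38) and Tpi1 (-0.41) having the smallest p and being called without sgControl 4 (adjusted p = 0.0405 and 0.0173), where 1 member was called up and 7 down, while 5 of 19 fell adjusted over the list alone and the list was called lower (camera adjusted p = 0.0405; adjusted p = 0.803 with an estimated correlation). The hypoxia list was called lower (adjusted p = 0.0368; adjusted p = 0.402 with an estimated correlation), with Vegfa and the collagen hydroxylase gene P4ha1 (-0.34) down and the histone demethylase gene Kdm3a (0.50) up of 20, each of these 3 called only without sgControl 4 among the fits that left 1 library out (adjusted p of up to 0.164). The list calls were lost without sgControl 4 or sgMFSD7C 4, and for glycolysis also without sgMFSD7C 2, with adjusted p of up to 0.18 for glycolysis and 0.0925 for hypoxia. The choline and phospholipid list was not called (adjusted p = 0.981, camera direction down and fry direction up), with the lysosomal phospholipid transporter Spns1 (0.78) and Flvcr1 up and the acyltransferase Lpcat1 (-0.41) down. Of 59 nuclear-encoded oxidative phosphorylation genes 1 fell, Sdha, from 82.5 ± 4.07 to 50.3 ± 2.37 FPKM (list adjusted p = 0.451). Spns1 and Sdha were called in each fit that left 1 library out, and Lpcat1 only in that without sgControl 4 (adjusted p of up to 0.181). Without sgControl 4, 2 hypoxia genes were called up and 7 down, 2 choline and phospholipid genes up and 3 down, and 1 oxidative phosphorylation gene up and 1 down. Mitochondrially encoded transcripts were not called (adjusted p = 0.908; mean -0.08, median 0.08), with mt-Co3 (-0.47) and mt-Co1 (-0.30) closest to the threshold. Without sgControl 4 the list mean turned positive, while mt-Co3 and mt-Co1 were at -0.28 and -0.13. Without sgMFSD7C 3 these genes were at -0.25 and -0.14.

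Cholesterol and fatty acid genes set sgControl 4 apart from every other library. The cholesterol list lay 1.05 above the control mean in sgControl 4, 0.51 and 0.54 below it in sgControl 2 and 3, and 0.17 to 0.21 below it in sgMFSD7C. None of its 19 members was called, Pmvk (-0.89, and -0.43 without sgControl 4) and Lss (-0.52, and -0.14 without sgControl 4) being closest, and the list was not called (adjusted p = 0.373). Without sgControl 4 it was called higher in sgMFSD7C (mean 0.33, adjusted p = 0.000548), with 9 members called up and none down, and without sgControl 2 or sgControl 3 it was called lower (mean of -0.45 to -0.47). Fatty acid synthesis genes lay 0.39 above the control mean in sgControl 4 and below it in the other 5 libraries, with no member called of 12 (list adjusted p = 0.44). Acacb (-0.40) and Fads1 (-0.43) were closest and were called without sgControl 4 (adjusted p = 0.0461 and 0.0219), where 5 members were called up and 3 down.

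Of the cell cycle lists, mitosis was called lower (camera adjusted p = 0.0202; adjusted p = 0.989 with an estimated correlation) with 1 of 31 members called, the kinesin gene Cenpe (-0.48), and this was lost without sgControl 4 (mean 0.01, adjusted p = 0.995). The S phase list was not called (adjusted p = 0.393), with the ribonucleotide reductase gene Rrm2 down (-0.46) of 32. Without sgControl 4, 7 S phase genes were called up and 1 down, 5 mitosis genes up and 3 down, 12 immediate early genes down and 2 ribosomal protein genes up. Immediate early genes were not called (adjusted p = 0.0797), Egr3 (-0.69) and Klf4 (-0.38) having the smallest p. They lay 0.93 below the control mean in sgControl 4 and were called lower without it (adjusted p = 2.33e-08), as were Egr3 and Klf4 (adjusted p = 0.0126 and 0.00791). The 71 cytosolic ribosomal protein genes were not called (adjusted p = 0.451; 0.00144 and higher without sgMFSD7C 3), with Rpl3 (-0.20) and Rpl18 (0.19) closest. Cenpe and Rrm2 lost their calls without sgControl 2, sgControl 3, sgMFSD7C 2 or sgMFSD7C 4, and Cenpe also without sgMFSD7C 3, with adjusted p of up to 0.149 and 0.103. In 7 lists fewer than 5 members were measured and no list test was made. These were erythroid and lung epithelial markers with no measured member, leukocyte markers and histones with 4 each, lymphatic endothelial and smooth muscle markers with 2 each, and other cell line markers with 1. The only called gene among them was Cd74, which takes part in class II antigen presentation, from 151 ± 13.7 to 104 ± 2.38 FPKM (-0.53, adjusted p = 0.0203), called only without sgControl 4 among the fits that left 1 library out (adjusted p of up to 0.113).

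**Figure D4:**
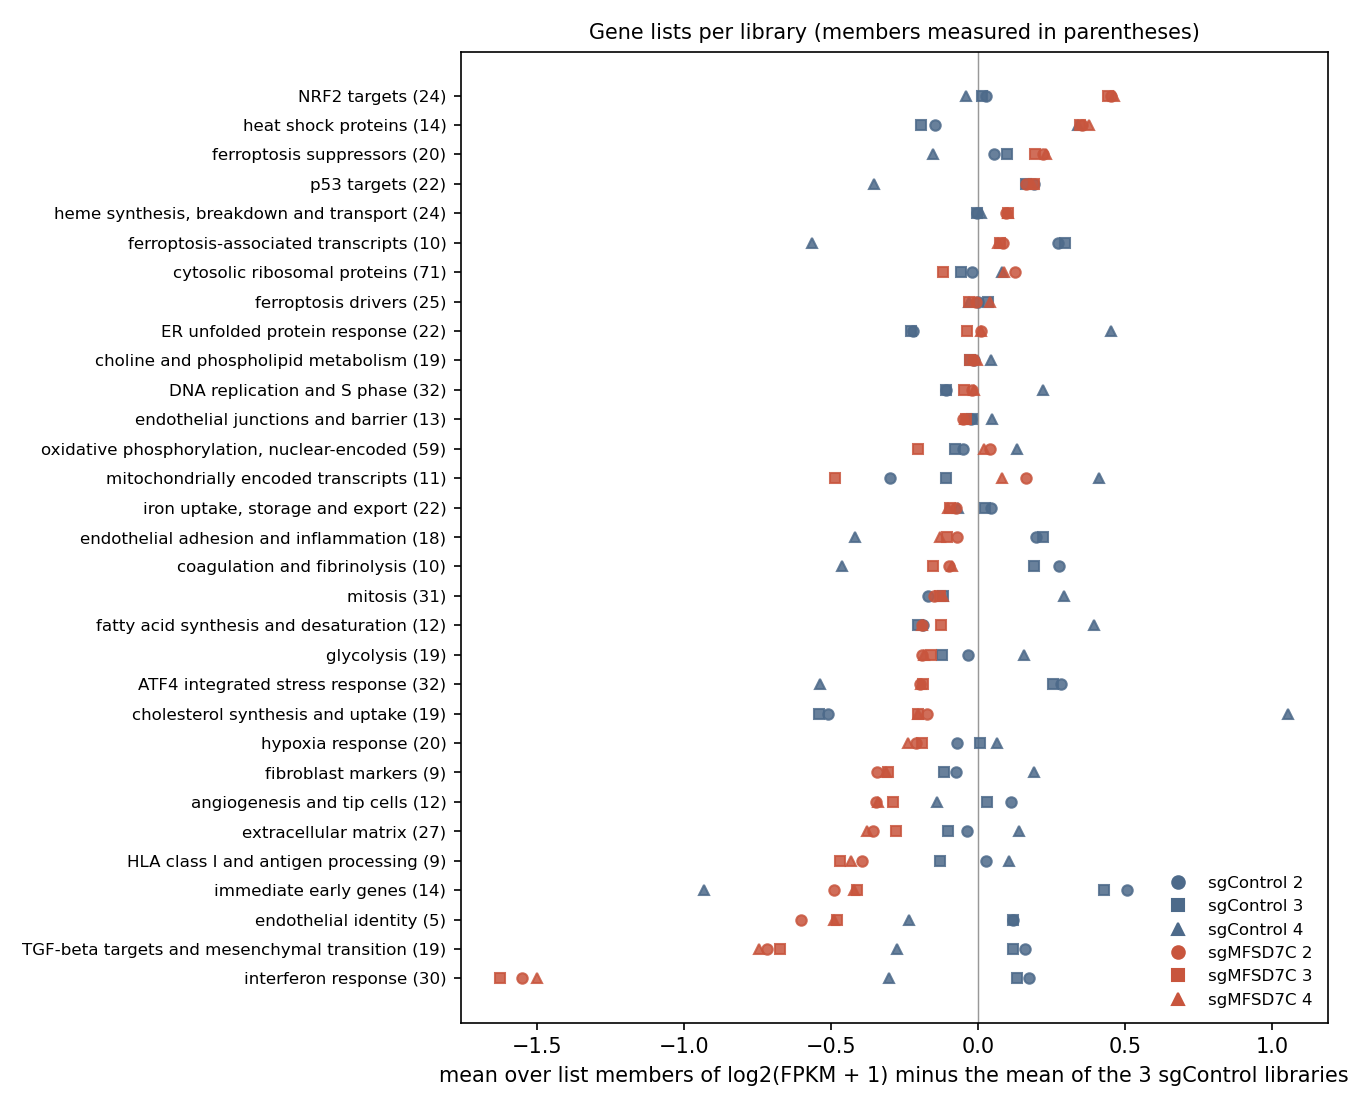
Mean over the members of each tested list of log2(FPKM + 1) minus the mean of the 3 sgControl libraries, for each of the 6 libraries of the replicated table; points are libraries, and the number of measured members is in parentheses. The sgMFSD7C libraries lie 1.5 to 1.63 below the control mean for the interferon response and 0.44 to 0.46 above it for NRF2 targets, and sgControl 4 lies 1.05 above it for cholesterol genes.

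In the single pair, most genes were listed at 0 and no change could be tested. Hmox1, Gpx4, Slc7a11, Fth1 and Flvcr1 were at 0 in both libraries, as were all measured heme, NRF2 and interferon genes of the fixed lists, and so were the cytoskeletal gene Actb and mt-Co1, which are abundant in the replicated table. Tfrc was at 3.16 FPKM in sgControl 1 and 22.1 in sgMFSD7C 1, from 1 and 7 reads. Acsl4 was at 47 and 7.23 FPKM, from 13 and 2 reads. The 6 highest ratios were those of Cks2, Map7d1, Srsf9, Srsf7, Sfn and Rtn4rl2, each listed at 0 in sgControl 1 and resting on 4, 18, 8, 11, 7 and 5 reads in sgMFSD7C 1. The 6 lowest were those of Pcnp, Twist1, Hoxa2, Ndel1, Rnf19b and Gabarapl1, each at 0 in sgMFSD7C 1 and resting on 21, 7, 7, 11, 9 and 5 reads in sgControl 1. Of 1706 genes with FPKM of at least 1 in either library, 1060 differed at least 2-fold, 500 higher and 560 lower in sgMFSD7C 1, with a median of 7 reads per gene over both libraries. For 297 of the 1060 the exact 95% binomial interval of the read ratio excluded equal levels, which compares these 2 libraries and not the conditions.

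Of the lists with at least 5 listed genes in the single pair, the 5 ferroptosis drivers had a median log2 ratio of -1.60, at percentile 3.51 of random lists, and the 6 iron genes 0.38, at percentile 74.8. The 5 junction genes had a median of -2.27 (percentile 16.2), the 6 angiogenesis genes -2.03 (percentile 8.56) and the 9 TGF-beta list genes -0.22 (percentile 39). These describe 2 libraries and have no replicate check.

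The single pair and the replicated table could be compared at few genes. Of the 862 called genes, 77 had a value in the single pair and 47 of these (61.0%, exact binomial 95% interval 49.2 to 72.0) had the same sign there. Random sets of 77 genes matched on expression gave a median of 53.2%, with 95% of them between 42.9% and 63.6%, so the share lay inside their range. Phlda3 (75.2 and 226 FPKM), Vegfa (73 and 13.7 FPKM) and Far1 (31.5 and 9.71 FPKM) had the same order in sgControl 1 and sgMFSD7C 1 as in the replicated table, and Id2 (16 and 144 FPKM) the opposite order. High FPKM values in that pair can rest on few reads, the median being 7 per listed gene over both libraries. These orders have no replicate check. The other 785 called genes were under 1 FPKM in both libraries there or had equal values in them.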

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

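The limma-voom fit was chosen after seeing the data and the other alternatives before it. With genes called 862 (355 higher, 507 lower), the count left the range of 1.5-fold without a filter (340; 103 higher, 237 lower), with a minimum absolute log2 fold change of 1 (172; 21 and 151) and over all 8 libraries with the table as a term (0; 0 and 0 by limma, with 2129 genes at an unadjusted p under 0.05). With limma-voom the number of genes higher in sgMFSD7C was 665. Leaving out 1 library gave 150 to 3332 genes changed, sgMFSD7C against sgControl, 19 to 1664 genes higher in sgMFSD7C and 131 to 1668 genes lower in sgMFSD7C, the lowest without sgMFSD7C 2 and the highest without sgControl 4, and all 862 were among the 3332. No called gene shared with another fit changed sign. Settings other than these and the replicate block gave 731 to 1254 genes. Whether equal numbers mark paired libraries is not known. Same-numbered libraries had correlations of deviations of -0.033, -0.029 and -0.028, which show no pairing. With 3 libraries per group and sgControl 4 apart from the other controls, they cannot exclude a modest shared effect. A replicate block gave 212 genes (32 higher, 180 lower), 209 of them among the 862. Of 15 called lists, 0 were called by camera with an estimated correlation (3 at an unadjusted p under 0.05) and 5 by fry, which asks another question. Of the called lists that fry did not call, its adjusted p was 0.0531 for extracellular matrix and 0.0576 for angiogenesis. It was 0.0675 for ferroptosis suppressors and for fibroblast markers, 0.0833 for hypoxia and 0.212 for heat shock and for glycolysis. For p53 targets, mitosis and ATF4 it was 0.535, 0.766 and 0.866. Leaving out 1 library, list means ran from -0.12 to 0.22 (ER unfolded protein response), -0.47 to 0.33 (cholesterol synthesis and uptake) and -0.22 to 0.012 (mitosis), each highest without sgControl 4. Among single lists 47 results lost and 10 gained a call, and among single genes 292 lost and 25 gained one. The share with the same direction in the single pair was 72% without a filter and 60% to 78.6% without 1 library. These fits called other numbers of genes, and no range of random sets stands beside the shares. They therefore do not show that the single pair and the replicated table move alike. Median-ratio scaling of the single pair had a factor of 1 and tested nothing. With FPKM of at least 5 Flvcr2 gave no value. Where no value shows the cause, the cause was not tested. Depth limits the single pair, with 49972 and 52377 reads.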

Other observations

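The tests of explanations and the counts over splits in this part were chosen after the results they bear on were seen; leaving out each library was planned before. The libraries differ in further ways that belong to no comparison of groups. In sgControl 4, the ferroptosis-associated transcripts lay 0.57 below the control mean on the log2 scale, coagulation genes 0.46 below and endothelial adhesion genes 0.42 below, while unfolded protein response genes lay 0.45 above and mitosis genes 0.29 above. Hmox1 was at 18.3 FPKM there, against 38.9 and 42.9 FPKM in sgControl 2 and 3. In sgMFSD7C 3, mitochondrially encoded transcripts lay 0.49 below the control mean, against 0.16 and 0.08 above it in sgMFSD7C 2 and 4, and the small RNA gene Gm23935 was at 24969 FPKM against a highest value of 7604 FPKM in the controls.

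The 6 libraries allow 10 splits into 3 and 3, so no share under 0.05 can be had. The real split called 862 genes and was the 1 of the 10 with as many, the highest of the others being 0. It called 15 lists, and 3 of the 10 splits, the real one included, called as many, the others ranging from 11 to 17. A list call by camera at the preset correlation therefore does not by itself tell the real grouping from others.

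Hmox1, Slc48a1, Flvcr1 and NRF2 targets were higher in sgMFSD7C. These differences did not need sgControl 4, since without it Hmox1, Slc48a1 and Flvcr1 were still called (limma adjusted p = 3.04e-05, 0.000232 and 0.00571). That fit called 3332 genes and kept all 862, so this check sets no called gene apart from the rest. Flvcr1 lost its call in other fits that left out a library, as given above. Without sgControl 4 the NRF2 list was called too (camera adjusted p = 6.83e-07, and 0.149 with all 6 libraries and an estimated correlation), though other splits also called lists. A candidate explanation, as a hypothesis, is more free heme in these cells, which would lower Alas1, the heme-repressed first enzyme of heme synthesis. Alas1, picked outside the rule for named genes and already known not to be called, had a log2 fold change of -0.29 (95% interval -0.49 to -0.10, limma adjusted p = 0.0782), and 12.6% of the genes tested also had an interval wholly below 0. Its adjusted p ran from 0.0364 without sgControl 4, where it was called, to 0.246, and any other difference between the cultures stays open. With Flvcr2 near 0 in the control libraries, a link to loss of MFSD7C was not shown either.

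The library sgControl 4 stood apart from sgControl 2 and 3. Its depth, 15096677 reads, lay inside the range of the other 5 libraries, which argues against depth. A swap with an sgMFSD7C library would need 1 of those out of place, and the lowest correlation between them, 0.983, was above the highest between groups, 0.963. Another culture or batch for sgControl 4 (PC2 score -35.4, with no other library on its side) stays open, because the labels give no batch. A wrong label of sgControl 4 alone, or an exchange with a sample outside these 6, needs no partner among them and stays open too, so the label of sgControl 4, and with it every sgControl mean, is in doubt, and no biological explanation was tested.

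Abundant transcripts of the replicated table were listed at 0 in the single pair. The counts argue against lower depth alone, for RNA of the same kind, since the lowest mitochondrial share of the replicated table would give 507.1 reads in the shallower library and 0 were found, with an upper 95% limit of 3.69. Human RNA counted on mouse gene models may give few genes and no mitochondrial reads, and the share in the pair was 0%, but it was the value that raised the idea, and no mouse genome was used here to test it. In the replicated libraries, 1.01% to 1.63% mouse mitochondrial reads and endothelial markers such as Pecam1 near 0 argue against RNA of the labelled human line. That they hold mouse RNA in its place is a hypothesis that was not tested with a mouse genome. No biological explanation was tested.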
